A study of Zea mays with 4 samples.

How the data were processed

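CUT&Tag was run on endosperm of maize (Zea mays) with an antibody against ZmICE1a, a basic helix-loop-helix transcription factor. In CUT&Tag the antibody brings a Tn5 transposase to the bound protein, and the transposase cuts and tags the DNA around it, so that sequenced fragments pile up at bound sites. Per the labels, nuclei came from about 100 mg of endosperm powder, the antibody was used at 20 μg/mL for 2 h, the secondary antibody at 10 μg/mL, the transposome for 1 h, and tagmentation ran at 37 °C for 1 h. The labels give 4 libraries, 2 of the wild type and 2 of a mutant, each group with biological replicates 1 and 2.

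The authors deposited 2 peak lists. Per the labels, the wild-type and the mutant library of replicate 1 both belong to list 1, and those of replicate 2 both belong to list 2. The labels do not say how the pair of libraries was used for a list. The submitters' processing notes name fastp 0.23.1, Bowtie2 2.4.1, SAMtools 1.12 and MACS2 2.1.0, with no order or settings. Names of unplaced contigs in the deposited lists are those of the B73 version 4 assembly, and all coordinates are given in that assembly, counted from 1. Each peak has, as the authors' values, a start, an end, a summit, a score, a fold enrichment over the local background, and the −log10 of the p-value and the q-value at the summit. The deposited score was within 1 of 10 times the −log10 q in all 14475 peaks of list 1 and all 17518 of list 2. The deposited fold enrichment is a linear ratio with a pseudocount of 1 on both sides, and this lowers the fold of peaks with few control fragments. The lowest −log10 q was 2.04 in list 1 and 2.02 in list 2. These fold and −log10 values were used to describe, rank and filter peaks, and their ranks were compared between lists over shared regions.

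Neither fragment numbers nor library depths were given as such. They were worked out from the deposited values, since the fold and the p-value of a MACS2 peak are both set by the number of treatment fragments at the summit and by the control background there. For each peak the whole number of treatment fragments and the control background that give both listed values were solved for, with up to 1000 fragments tried and a tolerance of 0.001 in −log10 p. This succeeded for 100% of the peaks of each list. In list 1 it needed the treatment to be scaled by 0.650, since unscaled treatment numbers accounted for 0.304% of its peaks. In list 2 the treatment was unscaled and the control was scaled by 0.986. Both lists were thus called with a second library as control, and the words treatment and control below stand for these roles. Which genotype had which role is not given in the sources used here. On 2000 simulated peaks per list the procedure recovered 100% of the fragment numbers. In list 1, 0.249% of the peaks had a second solution, and the one closest to the listed p-value was kept.

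The recovered background also shows how the caller set it. It was the number in a fragment-sized window (350 bp in list 1, 343 bp in list 2) for 62.2% and 63.5% of peaks, a number scaled from a 1 kb window for 30.5% and 29.3%, a number scaled from a 10 kb window for 3.26% and 3.96%, and the genome-wide background for 4.05% and 3.29%. The genome-wide background was 0.626 control fragments in list 1 and 0.918 in list 2. A peak was counted as at the genome background when its control was within 1% of that value, and such a peak has fewer control fragments in all 3 windows than the genome average. Relative depth follows from the scaling: the treatment library of list 1 was 1.54 times as deep as its control, and that of list 2 was 0.986 times as deep as its control. If the same genome size was set for both lists, the treatment libraries differed in depth by 1.04 times and the control of list 1 had 0.668 times the depth of the control of list 2. Total depth is unknown. Intervals on fragment numbers are exact Poisson intervals at 95%, intervals on shares are exact binomial intervals, and both cover counting error only, since PCR copies are not independent molecules.

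Shared peaks overlapped by at least 1 bp, and overlapping peaks of both lists were merged to shared regions. The overlap was compared with 1000 random placements of the list 2 peaks on their own chromosome, one-sided. Correlations across regions had two-sided permutation p-values from 100000 resamples, adjusted over the 6 quantities by the Benjamini-Hochberg method. Regions are not independent replicates. The spread between lists was also simulated, after the observed value had been seen, for independent libraries with 5 assumed peak profiles of 20000 peaks each. Windows of 100 kb with 5 or more shared regions were compared with 1000 random placements of the regions within their own 5 Mb bin. The placement test called 1.01% of the peaks shared on simulated lists with no planted overlap and 49.7% with 50% planted. The overlap test, the correlations of fold and −log10 q, their alternatives and the rule for named regions were fixed before the data were examined. The rule took the 10 shared regions with the highest fold, ranked by the lower of both lists' folds, for the case that gene positions could not be used.

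Several tests were chosen after the peaks had been looked at: the correlations of fragments, control and ratio without pseudocount, the comparison of shared with unpaired peaks (two-sided permutation test), the 100 kb windows, the density at chromosome ends (the part at either end against the 2 in the middle of 10 equal parts, exact two-sided sign test over 10 chromosomes), the place of the 100 strongest regions, and a scan for a stretch of peaks at the genome background. The scan searched list 1 for the stretch in which the share of such peaks was raised most towards 25%, and the stretch it found was tested on list 2 by rotating the peaks along the genome through all 17344 positions, one-sided. On 1 simulated list with a planted block, in which 25% of peaks were flagged at random, the scan covered 98.8% of the block. How far it ran beyond the block and how often it finds false stretches were not measured. The check thus does not show how exact the ends of a stretch are. Ratios of medians inside and outside the stretch, and ratios of the share at the background in the middle 50% of chromosomes over the rest, have intervals from 1000 bootstrap draws of 1 Mb blocks. For the strongest regions, single regions were drawn in place of blocks. The place of the strongest regions was first tested by the same kind of rotation and then, after that result had been seen, by exchanging 216 blocks of 10 Mb at random 100000 times, one-sided. Both p-values are given. Chromosome lengths were taken as the position of the last peak end in either list.

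A genome sequence and gene models of the B73 version 4 assembly were not used here. The planned placement of summits relative to genes, the tests of E-boxes and other motifs, the scan of 6-mers and the tests of gene lists were therefore not run, and regions are named by position only. Peaks on unplaced contigs and on the mitochondrial genome were left out of the comparisons. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.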

Results

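Binding of ZmICE1a in maize endosperm was mapped by CUT&Tag in 2 wild-type and 2 mutant libraries, which entered 2 peak lists of 1 wild-type and 1 mutant library each. The series asks which sites the factor occupies while the endosperm divides its resources between storage and defence. List 1 held 14475 peaks and list 2 held 17518. The median peak was 539 bp wide in list 1 and 546 bp in list 2, and no peak was narrower than 343 bp or wider than 4873 bp. Each list had been called with 1 library as treatment and another as control, so a peak marks a site with more fragments in the treatment than in the control. The genotype behind each role is not given in the labels, so no value below can be assigned to the wild type or to the mutant.

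The authors' fold enrichment had a median of 5.41 in list 1 (interquartile range 4.13 to 7.29) and 4.86 in list 2 (3.72 to 6.51). It reached 50.6 in list 1 and 57.2 in list 2. The median summit had 55 treatment fragments over a control background of 5.25 in list 1, and 40 over 7.0 in list 2. The list 1 background is in fragments of the shallower control library, and its treatment library was 1.54 times as deep as that control. The treatment library of list 2 was 0.986 times as deep as its control.

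Most sites of list 1 were found again in list 2. On chromosomes 1 to 10, 11527 of 14358 list 1 peaks overlapped a list 2 peak (80.3%, 95% exact binomial interval 79.6 to 80.9), and 11468 of 17344 list 2 peaks overlapped a list 1 peak (66.1%, 65.4 to 66.8). Random placement on the same chromosome gave 1.06% and 0.871%, and no placement reached the observed share (p = 0.001, one-sided permutation of positions, the smallest that 1000 placements can give). Together the overlapping peaks formed 11310 shared regions with a median length of 714 bp, and 96.9% of these joined 1 peak of each list. Their summits lay close together, with a median distance of 37 bp and 80.4% within 100 bp. The shared regions covered 0.435% of the span of the chromosomes, at 5.37 regions per Mb. A lower fold above 10 was seen in 535 of them and above 20 in 31.

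Peaks found in 1 list were the ones with fewer fragments. The 2831 list 1 peaks without a partner (19.7%) had a median of 30 treatment fragments, against 63 in the shared ones. The 5876 list 2 peaks without a partner (33.9%) had 23, against 53. Their median folds differed less from those of shared peaks: 5.28 against 5.49 in list 1, and 4.71 against 5.003 in list 2. Shared peaks were higher by a mean log2 fold of 0.12 in list 1 and 0.14 in list 2 (p = 1e-05 each, permutation test, the smallest that 100000 resamples can give). Among peaks with a −log10 q of at least 5 the difference was 0.06 and 0.08. The direction turned without the pseudocount: the median depth-adjusted ratio was 6.34 in shared and 7.15 in unpaired list 1 peaks, and 5.51 and 5.75 in list 2, with mean log2 differences of -0.10 (p = 1e-05) and -0.026 (p = 0.04, permutation tests). Which kind of peak was stronger thus depends on the measure. These permutations treat the peaks of 1 list as independent, though neighbouring peaks may not be, and their p-values do not measure replication. By −log10 q, 99.3% of list 1 peaks above the upper quartile were shared and 55.3% of those below the lower quartile, and for list 2 the shares were 96.5% and 35.0%. Whether an unpaired site differed between the replicates was not tested.

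The strength of a site was correlated between the lists, more closely for fragments than for fold. The folds of both lists lay within 1.5 times of each other at 73.6% of the shared regions, the SD of the log2 ratio of list 1 over list 2 was 0.53, and 59.8% of regions were higher in list 1. Over the 11310 shared regions the fold enrichment had a Spearman rho of 0.656 and a Pearson r of 0.674. The treatment fragments at the summit had a rho of 0.951 and an r of 0.967, and the control background had 0.90 and 0.934. All of these had an adjusted permutation p of 1e-05, the smallest the resamples can give, in a family of 6 quantities. These are correlations across regions, which are not independent replicates, and the 2 lists were not shown to be independent either. Among regions from the stronger peaks of each list (fold at or above the list's median, 4450 regions) the rho of the fold was 0.421. That cut narrows the range of the fold in both lists, which by itself lowers a rho, so the value does not show that stronger sites agree less.

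**Figure D1:**
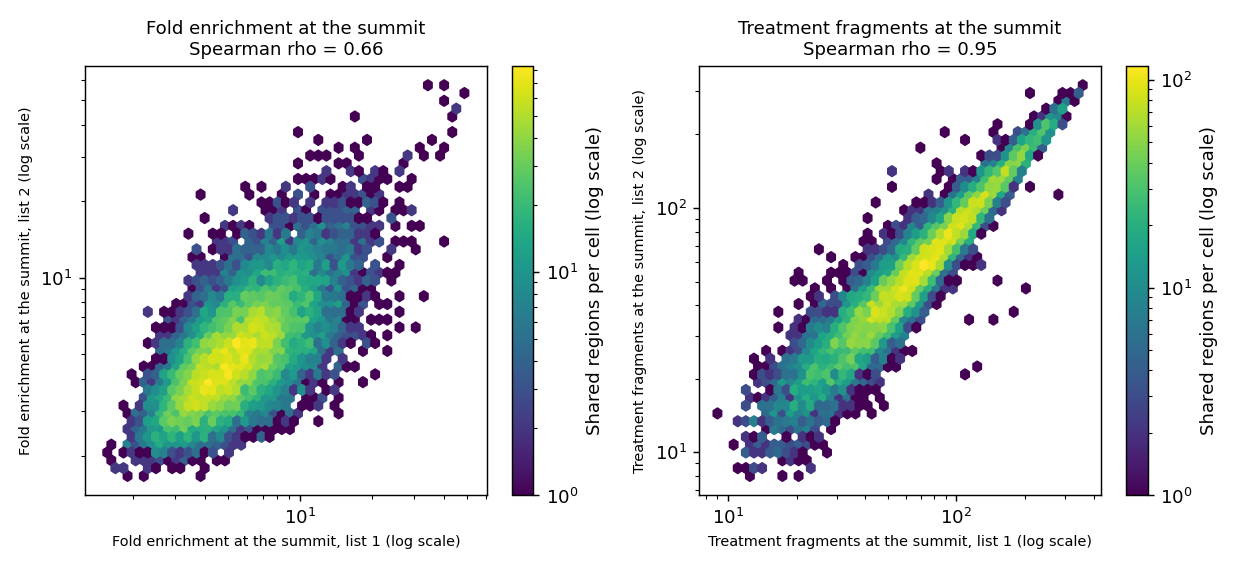
Fold enrichment (left) and treatment fragments (right) at the summits of the 11310 shared regions, list 1 on the x axis and list 2 on the y axis, both on log scales, with colour for the number of regions per cell. The fragments lie on a narrower band than the fold, with Spearman rho of 0.951 against 0.656.

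At 763 shared regions with summits within 5 bp of each other, the fragment numbers of both lists differed by less than Poisson sampling noise. After adjustment for depth, the chi-square per degree of freedom was 0.549 for the control and 0.878 for the treatment, where freely placed independent counts give 1. Choosing summits and control windows lowers it: in simulated independent libraries it was 0.834 to 0.988 for the control and 0.762 to 0.941 for the treatment over 5 assumed peak profiles. The treatment value lay in its simulated range and the control value below its own. The simulated control was chosen between the fragment-sized and the 1 kb window only. Independence was not shown, so the 2 lists were counted as 1 sample, and no SD across replicates is given.

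The 10 strongest shared regions, ranked by the lower of both folds, lay on chromosome 1 (1 region) and chromosome 3 (9 regions). The strongest was chromosome 1, 298605214 to 298606174 (B73 version 4). It had a fold of 50.6 in list 1 and 53.0 in list 2, from 125 treatment fragments (95% Poisson interval 104 to 149) and 100 (81.4 to 122). Next came chromosome 3, 140532935 to 140534029, with folds of 44.2 and 46.7, and chromosome 3, 107891046 to 107892015, with 44.2 and 44.8. Chromosome 3, 115133400 to 115135517, was the widest of the 10 at 2118 bp and had the most treatment fragments, 206 in list 1 and 175 in list 2, with folds of 43.5 and 44.5. The region at 161792224 to 161793618 of chromosome 3 had folds of 40.2 and 51.4, and that at 95204013 to 95205505 had 38.8 and 55.6. Those at 138555015 to 138556106 and at 159329767 to 159331158 had 42.6 and 38.3, and 35.4 and 35.7. The remaining ones, at 160392181 to 160394127 and 50171585 to 50172658, had 34.2 and 57.2, and 41.1 and 32.8. Control fragments were nearly absent at these sites: the control background was at most 2.1 in list 1 and 3 in list 2, and 5 of the 10 were at the genome-wide background in both lists. Of the 10, 7 were at that background in list 2, and there the fold rests on the caller's floor. Genes at these positions were not analysed here.

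Shared regions were denser towards the chromosome ends. With each chromosome divided into 10 equal parts, the part at either end held 9.08 regions per Mb and the 2 parts in the middle 2.71 per Mb. The ratio of the outer to the middle count had a median of 2.77 over chromosomes and ranged from 2.16 on chromosome 4 to 6.21 on chromosome 2, with more regions at the ends on 10 of 10 chromosomes (p = 0.00195, exact sign test, two-sided). Per chromosome the density ran from 4.05 per Mb on chromosome 4 to 6.56 per Mb on chromosome 7. This comparison was chosen after the peaks had been looked at. Counts were not adjusted for gene density or for sequence to which reads can be mapped. Whether the gradient is particular to the factor was therefore not tested.

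**Figure D2:**
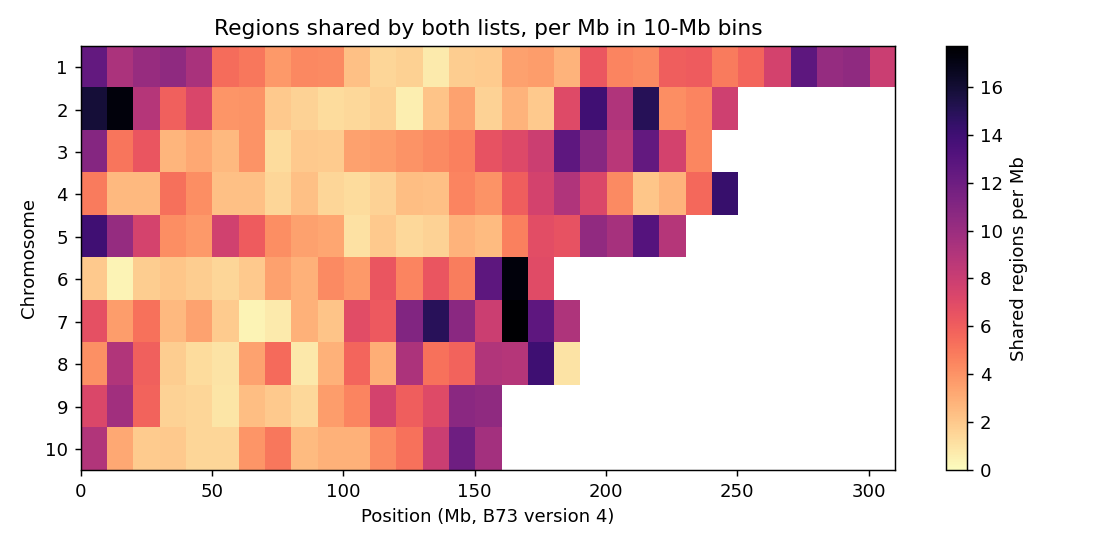
Shared regions per Mb (colour) in 10 Mb bins along chromosomes 1 to 10 (rows), with the position in Mb of B73 version 4 on the x axis. Bins towards the chromosome ends are darker, and the outermost of 10 equal parts together hold 9.08 regions per Mb against 2.71 in the middle.

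Chromosome 3 held more of the strongest regions than its size would give. It had 12.04% of all shared regions and 46 of the 100 strongest by fold, and chromosome 7 had 23 of these. Of the 31 regions with a lower fold above 20, 20 were on chromosome 3 and 6 on chromosome 7. Ranked by treatment fragments in place of fold, 15 of the top 100 were on chromosome 3. Random exchange of 10 Mb blocks gave p = 2e-05 for the count of 46 and p = 0.16 for the count of 15 (one-sided permutation tests). Rotation of the regions along the genome, an exact test over all rotations that was run first, gave p = 0.0623 for the count of 46, and so the excess did not pass 0.05 in that test. Over 8 rankings and list choices the rotation p ran from 0.0188 (the strongest 200) to 0.128 (treatment fragments), and 4 were below 0.05. Neighbouring blocks may not be independent, which would make the block p too small, while short rotations can leave clustered regions on chromosome 3. Neither was tested as the cause of the difference.

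The strong regions of chromosome 3 lay mostly in a stretch where many peaks had few control fragments at the summit. In list 1, the clearest excess of peaks at the genome-wide background ran from 29276257 to 161913791 of chromosome 3, and 120 of the 592 peaks there were at that background (20.3%), against 3.35% of peaks elsewhere. This stretch held 38 of the 100 strongest shared regions, 9 of the 10 named above and 469 of all 11310. Such an overlap is in part built in, since a low control raises the fold and the stretch was sought for low controls. The control was read at called summits only, so coverage of the stretch as a whole was not measured. In list 2 the same stretch held 138 such peaks of 723 (19.1%), against 2.60% elsewhere (p = 0.000865, exact rotation test, one-sided). The median control background was lower inside the stretch, at 2 against 5.6 in list 1 and 3 against 7.20 in list 2. Treatment fragments were lower as well, with medians of 39 against 55 and 29 against 41, while the fold was 1.23 times that outside in both lists. The stretch was sought after the peaks had been looked at, and its test in list 2 treats that list as separate from list 1, which the low spread between the lists leaves open.

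**Figure D3:**
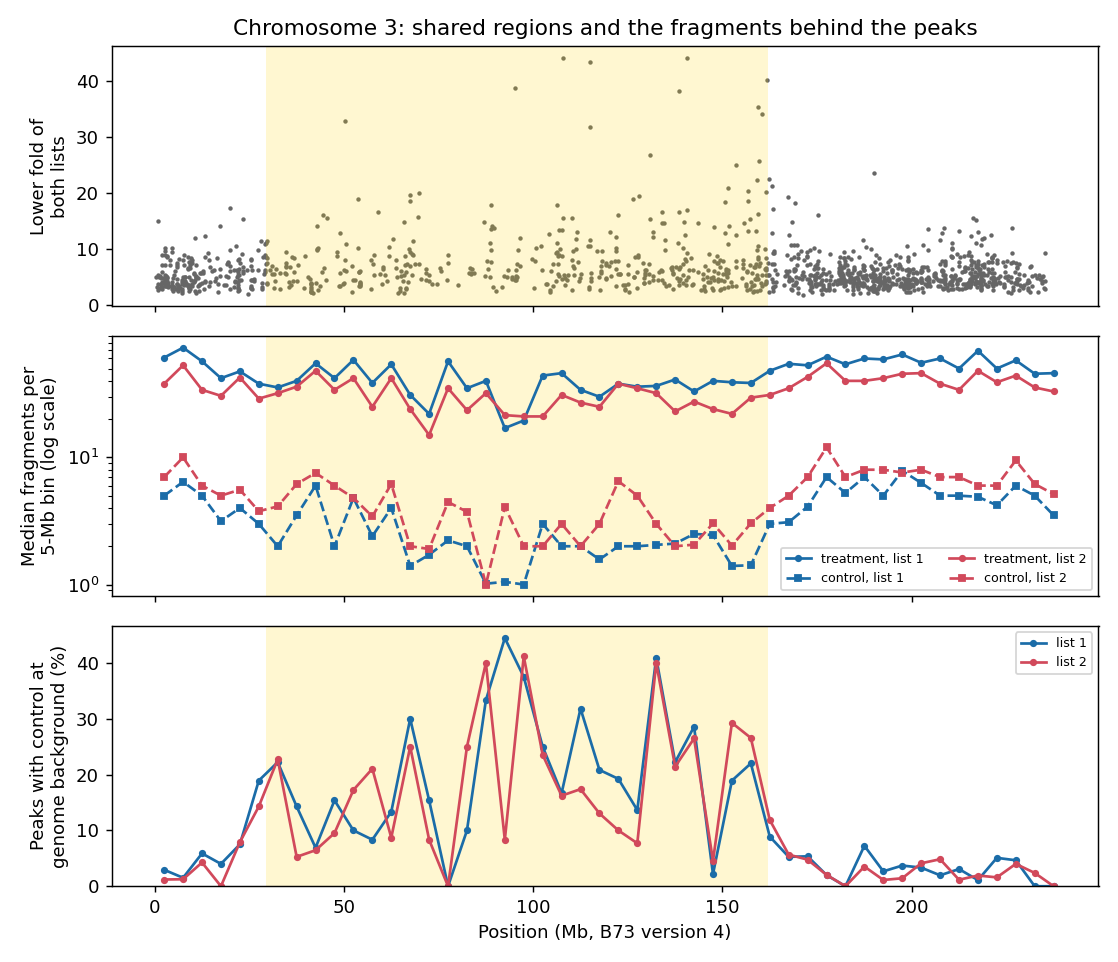
Chromosome 3 by position in Mb (x axis): the lower fold of both lists at each shared region (top), the median treatment (solid) and control (dashed) fragments per 5 Mb bin on a log scale (middle) and the percentage of peaks with the control at the genome-wide background per bin (bottom), with list 1 in blue, list 2 in red and the stretch from 29276257 to 161913791 shaded. Inside the shading 20.3% of list 1 peaks and 19.1% of list 2 peaks are at the background.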

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

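Values from sequences outside the comparisons come first here, and the tests of explanations for chromosome 3 were chosen after the result was seen. List 1 had 117 peaks on 50 unplaced contigs and list 2 had 173 on 70 contigs, each called above the control, and 94 shared regions lay on contigs. List 2 also had 1 peak on the mitochondrial genome, at 242614 to 243204, with a fold of 1.29 from 485 treatment and 382 control fragments.

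The stretch of chromosome 3 from 29276257 to 161913791 held 38 of the 100 strongest shared regions and 469 of all 11310. Peaks with the control at the genome background made up 20.3% of list 1 and 19.1% of list 2 peaks there, against 3.35% and 2.60% elsewhere. By number most such peaks lay elsewhere, with 461 against 120 inside in list 1 and 432 against 138 in list 2. A property shared equally by all chromosome interiors is argued against as the whole cause by the other 9 chromosomes. The share of peaks at the background in their middle 50% was 1.31 times that in the rest of them in list 1 (1.08 to 1.57) and 1.26 times in list 2 (0.999 to 1.54). On chromosome 3 the ratios were 3.86 (2.62 to 5.78) and 4.18 (2.77 to 6.45). The rise towards the middle was thus smaller on the other 9 together than on chromosome 3. Chromosome 3 was chosen for such peaks, which raises its ratios, and the intervals leave out differences between chromosomes. The comparison therefore does not decide whether a property of chromosome interiors is the cause. For stronger treatment signal, the 38 strongest regions inside had 0.830 times the list 2 treatment fragments of the 62 elsewhere, with an interval that includes 1 (0.681 to 1.13). Their median of 56 lay above the 53 of all shared regions. Their list 2 control was 0.493 times that of the 62 (0.382 to 0.686), with a median of 1.0 against 9.95 in all shared regions. These control values decide nothing, since the regions were picked by fold and the stretch for a low control. All peaks inside had 0.709 (0.643 to 0.750) and 0.707 (0.634 to 0.8) times the treatment fragments of those outside in lists 1 and 2. That goes against stronger treatment signal, but where the control is low weaker peaks pass the caller, so it stays open. A loss of control fragments stays open too, since the median list 2 control background of 0.416 times that elsewhere (0.371 to 0.530) comes from a stretch chosen for a low control in list 1, and the lists were not shown to be independent. Another haplotype in the control material, whose reads map less well to the assembly, may lower the control, but among peaks above the background the ratio was 1.31 times that elsewhere (1.204 to 1.37), where a mixture of lost and ordinary sites predicts 1, and since leaving out peaks at the background truncates the control, a lost haplotype and a real loss of signal cannot be told apart, and a difference between the wild type and the mutant stays untested because the labels do not say which library was the control.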

How the results depend on the processing

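The excess of shared over unpaired peaks in mean log2 fold reversed without the pseudocount, to -0.10 in list 1 and -0.026 in list 2. The fold and this ratio differ only by the pseudocount, which lowers the fold of peaks with few control fragments. The median control background was 2.8 in unpaired and 6.3 in shared list 1 peaks, and 4.0 and 9.95 in list 2. With a −log10 q of at least 5 the excess in mean log2 fold was 0.06 and 0.08. No other result reversed. The 14 alternatives for chromosome ends and chromosome 3 kept the call in 12 cases and lost it in 2. The 12 for shared peaks and 5 for correlations kept p at the smallest value their draws can give, which says little about stability. Settings for shared against unpaired peaks, for the density at chromosome ends, for chromosome 3, and for fragments and the ratio without pseudocount were chosen after seeing the data. The share of list 1 peaks found in list 2 was 73.9% with a reciprocal overlap of 50% and 64.1% with summits within 100 bp, and for list 2 it was 61.2% and 53.1%. It was lowest, at 62.4% and 51.6%, when both lists were cut to their stronger peaks (fold at or above the median). That cut also removes partners below the other list's median, so it does not show that stronger peaks are shared less. Against the full lists, 88.3% and 75.6% of peaks from the upper quartile of fold were shared. From the lower quartile, 81.5% and 65.2% were shared. All placement p-values were 0.001, also when peaks were moved by 5 to 50 kb, where chance rose to 2.15% and 1.78%. No peaks touched, so merging them changed nothing and tests nothing. The rho of the fold fell from 0.656 to 0.421 among stronger peaks, where the cut narrows the range of the fold and by itself lowers a rho. For other quantities the rho was 0.691 (ratio without pseudocount) to 0.951 (treatment fragments). The ratio of density at the ends over the middle was 2.79 to 2.81 with 1 list alone.

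The count of strongest regions on chromosome 3 lost its call in 2 settings. Ranked by treatment fragments it was 15 of 100 (permutation p = 0.16), and under exact rotation the count of 46 had p = 0.0623; of the 8 rankings and list choices, 4 had a rotation p below 0.05 (range 0.0188 to 0.128). With 1 list alone the count was 37 to 46 of 100. Over the block tests its p ran from 1e-05, the smallest possible, to 0.16. The cause was not tested for either. The share of list 2 peaks at the background in the stretch was 28.2% with a tolerance of 15%, 18.6% in shared peaks and 17.5% with a −log10 q of at least 5. In that order the exact one-sided rotation test gave p = 0.00156, 0.000436 and 0.00088. Shares outside the stretch at these settings are not given here, and a wider tolerance can raise the share there too.

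No paired analysis was possible because each list combines the wild-type and the mutant library of a replicate and carries no value per genotype. The alternatives set out in advance for gene positions, motifs, 6-mers and gene lists were not run, as these results were not computed. Unpaired peaks had medians of 30 and 23 treatment fragments, and whether depth left them unpaired was not tested.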

Other observations

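The tests of local clusters and of fragment noise below were chosen after the lists had been compared, except for the predicted correlation, and the places named were chosen after their values were seen. Shared regions came in local clusters. Of 21046 windows of 100 kb, 6840 held a shared region and 211 held 5 or more, where random placement within the same 5 Mb gave a mean of 43.3 and at most 63 (p = 0.001, one-sided permutation of positions, the smallest that 1000 draws can give). The densest was chromosome 5, 6700001 to 6800000, with 11 shared regions. Windows with 9 were chromosome 6, 169300001 to 169400000 and 168600001 to 168700000, chromosome 3, 218200001 to 218300000, and chromosome 5, 219100001 to 219200000. Their median lower folds were between 3.36 and 5.46. The random placement took no account of genes or of sequence to which reads can be mapped.

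The regions with the most treatment fragments were not those with the highest fold. Chromosome 8, 7618092 to 7619624, had 357 treatment fragments in list 1 and 318 in list 2, but control backgrounds of 93.0 and 139 and folds of 2.48 and 2.31. Chromosome 2, 59229414 to 59230845, had 346 and 299 treatment fragments with folds of 2.51 and 2.38. Chromosome 3, 886147 to 887422, had 337 and 298 with folds of 4.31 and 3.70. After chromosome 3, the stretch of list 1 with the next clearest excess of peaks at the genome background was chromosome 7, 121469744 to 125652118, with 12 of 53 peaks.

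The fold had a lower correlation between lists than the fragments behind it. Counting noise was weighed as an explanation, and the test could not decide it. Over 5663 regions with both controls counted in the fragment window, counting noise alone predicted a correlation of the log ratio of 0.355. The observed correlation was 0.693, so this noise model predicted more disagreement than was seen. That would be so if the noise was overstated or common to both lists. The share of counting noise in the disagreement stays open.

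The control numbers of both lists were closer than in simulated independent libraries, with a chi-square per degree of freedom of 0.549 against 0.834 to 0.988, while the treatment value of 0.878 lay within the simulated 0.762 to 0.941. Reads of 1 library behind both lists are a candidate explanation. So is the choice of the values, since a summit is the highest point of a peak and the background the highest of several windows, and both choices narrow the spread. The simulation included the choice of the summit, but for the control only the choice between the fragment-sized and the 1 kb window. The 10 kb window and the genome-wide background were not simulated. The assumed profiles took the control from the fragment window in 80.2% to 97.4% of peaks, against 62.2% in list 1. The control value of 0.549 therefore leaves both explanations open. No biological explanation was tested.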
